A study of Mus musculus with 28 samples.

How the data were processed

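RNA was sequenced from bone marrow-derived macrophages of FVB/Hsd mice on day 7 of differentiation. The cells carried a retroviral short hairpin against Wdr82 (sh1137), against Set1a together with Set1b, or against Pnuts, or a control vector that was empty or held a scrambled hairpin. They were untreated or received lipopolysaccharide (LPS, a bacterial cell wall component) at 10 ng/ml, and 1 set also received DRB, an inhibitor of RNA polymerase II elongation. The RNA was either polyA-selected or labelled with 4-thiouridine (4sU) for 45 min before harvest, so that 4sU RNA is enriched for newly made transcripts. LPS times were taken from the sample titles.

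The authors deposited 6 tables, which hold 28 libraries with 1 library per condition. Each table gives 36806 Ensembl mouse genes (33411 symbols) and, per the file headers, an FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) for each library. A lower and an upper confidence bound and a status accompany each FPKM. According to the submitters' processing notes, reads were aligned to mm9 with TopHat 1.3.1 and quantified with Cufflinks 2.1.1 and Cuffdiff 2.1.1. The annotation, the scaling between libraries and the level of the confidence bounds are not given in the sources used here. The tables hold no read counts, so the depth of each library is unknown and no counting intervals were computed.

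Ratios were taken within a table only, as log2((FPKM + 1)/(FPKM + 1)), that is with a pseudocount of 1 FPKM. A gene was tested when its FPKM was at least 1 in either library of the pair and its status was OK in both, and it was called when the ratio was at least 2-fold. Because each condition has 1 library per set, a single pair of libraries was not tested and has no p. Added after seeing the data, a limma fit over the 4 sh1137 to control ratios of the unstranded set (untreated, 45 min, 2 h and 4 h, 3 residual degrees of freedom, adjusted p under 0.05) treated the times as repeats. Beside the calls of the knockdown and DRB comparisons stands the number of genes whose deposited bounds did not overlap. The 30 comparisons were 14 of knockdown against control, 14 of LPS against untreated cells with the same vector, and 2 of DRB against no DRB. The LPS comparisons of the unstranded table share an untreated library per vector. The difference between the LPS ratio in the knockdown and that in the control was computed per gene.

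The named genes follow a rule set before the data were examined. They are the targeted genes and their partners, the 10 highest and the 10 lowest ratios per comparison, and up to 4 members per gene list. The FPKM had to reach 5 in the higher library, and small RNA and pseudogene names were excluded. For the highest and lowest ratios of knockdown comparisons, the direction also had to be the same at each LPS time of the table, which was not asked of list members. A symbol present more than once was taken from its entry with the highest mean FPKM. Genes named outside this rule are said to have been chosen after their values were seen.

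The 24 gene lists were also fixed before the data were examined. They cover the targeted genes, Set1 COMPASS and PTW/PP1 partners, termination and 3' end processing factors, immediate early genes, inflammatory LPS genes, and interferon and late LPS genes. Markers of macrophages, neutrophils, dendritic cells with MHC class II, lymphocytes, erythroid cells, stroma, and mast cells with basophils form a further part. The remaining lists are p53 targets, the integrated stress and unfolded protein response, heat shock genes, cell cycle genes, cholesterol and lipid synthesis, and noncoding and small RNA host transcripts. Replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, snoRNA with scaRNA and snRNA genes, and microRNA genes complete the set. For each list with at least 5 measured members, the median log2 ratio was ranked among 10000 random lists of the same size, matched on expression in 20 bins. A list was called outside the random range below percentile 2.5 or above percentile 97.5. This rank describes these libraries and does not measure the spread between cultures.

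Shared calls were counted beside the number that independent lists would give. Genomic length and the gap to the nearest locus with an active gene (FPKM of at least 20) were read from the loci in the tables, for genes that had a locus to themselves. The gap was measured without strand, which the tables do not hold, and for genes with a mean FPKM under 5. The procedure was tested on simulated data built from the untreated libraries of 2 tables, with 50 genes for each of 4 kinds of change. It recovered 50 of 50 genes for each change in the stranded Wdr82 set, and in the Pnuts set 47 of 50 for a 3-fold decrease and 50 of 50 for the others. No unchanged gene was called, and unchanged lists of 20 genes lay outside the random range in 12 of 200 and 6 of 200 draws. The simulated noise was the same for all genes and far below a 2-fold change, so the absence of false calls was almost certain in advance. Only genes with an FPKM of at least 5 were changed. The real spread between cultures is unknown, so these rates do not carry over to the real pairs.

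Alternatives set beforehand were a pseudocount of 0.1 FPKM, no filter on FPKM, a filter of 5 FPKM, centring on the median gene, and leaving out time points. After seeing the data, counts without small RNA, clone and predicted gene names and list totals without the snoRNA and microRNA lists were added. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. No library was left out.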

Results

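The data comprised 28 RNA libraries of mouse bone marrow-derived macrophages in 6 sets. In 4sU RNA, Wdr82 was depleted with hairpin sh1137 in an unstranded set (untreated cells and 45 min, 2 h and 4 h of LPS), a stranded set (untreated cells and 1 h of LPS), and a set given LPS for 45 min with or without DRB. A polyA set held untreated cells and cells after 4 h of LPS. The Set1a+Set1b and Pnuts sets were stranded 4sU RNA from untreated cells and after 45 min of LPS. The control was an empty vector in the unstranded, stranded and polyA Wdr82 sets, and a scrambled hairpin in the DRB, Set1a+Set1b and Pnuts sets. Where the control was empty, the loss of Wdr82 is not separated from carrying a hairpin. Each condition had 1 library per set, so the differences of a single pair of libraries were not tested, while the sh1137 effect over the 4 times of the unstranded set was. Between 11456 and 13518 genes reached 1 FPKM per library, and 0.696 to 0.758% of the genes had a status other than OK. Relative depth, read from the commonest ratio between the values of low genes, differed within a set by 1.59-fold (Set1a+Set1b) to 3.35-fold (polyA). Values are FPKM, pairs of values give control before knockdown (or untreated before treated), and log2 ratios include a pseudocount of 1 FPKM.

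The first question was how far the targeted transcripts were reduced. Wdr82, a subunit of the Set1 histone methyltransferase complexes and of a phosphatase complex with PNUTS, was lower with sh1137 in each of the 10 Wdr82 pairs. In polyA RNA its FPKM was 16.8 (deposited bounds 5.45 to 28.2) in the control and 3.71 (1.22 to 6.199) with sh1137, and 22.6 and 4.03 after 4 h of LPS. In unstranded 4sU RNA of untreated cells the values were 21.6 and 10.3, and in stranded 4sU RNA 22.7 and 13.4. Ppp1r10, the gene that encodes PNUTS, was higher and not lower in the libraries labelled Pnuts sh, at 89.5 (bounds 41.2 to 138) in the control and 144 (57.4 to 231) in the knockdown of untreated cells, and 203 and 332 after 45 min of LPS. Ppp1r10 was also higher with sh1137 in all 10 Wdr82 pairs, for example 52.4 and 111 in untreated unstranded 4sU RNA and 9.54 and 30.9 in polyA RNA. In the Set1a+Set1b set, Setd1a, the gene for SET1A, was 16.1 and 14.8 in untreated cells and 18.1 and 13.5 after LPS. Setd1b was 11.3 and 11.8 in untreated cells and 10.5 and 6.70 after LPS, so neither gene was 2-fold lower. The loci in mm9 are chromosome 9, 106073259 to 106094747 for Wdr82 (ENSMUSG00000020257), chromosome 17, 36053378 to 36069226 for Ppp1r10 (ENSMUSG00000039220), chromosome 7, 134920183 to 134947316 for Setd1a (ENSMUSG00000042308) and chromosome 5, 123497381 to 123700140 for Setd1b (ENSMUSG00000038384). The Wdr82, Ppp1r10 and Setd1a loci hold 2 genes each and the Setd1b locus 8, so reads of overlapping genes are not separated there in unstranded libraries.

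**Figure D1:**
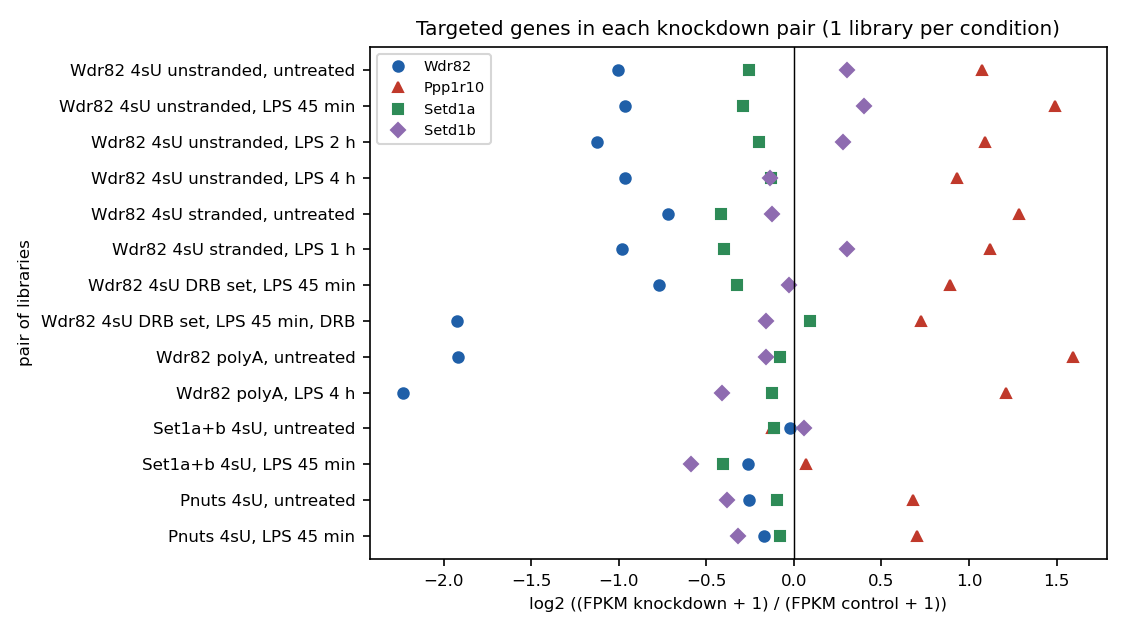
Log2 ratio of knockdown over control (x axis) for the 4 targeted genes in the 14 knockdown pairs (y axis), 1 point per pair of libraries. Wdr82 lies below 0 in each of the 10 Wdr82 pairs, and Ppp1r10 lies above 0 in those pairs and in both Pnuts pairs.

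In untreated macrophages depleted of Wdr82, 4sU RNA of genes such as Mmp27, Pla2g7, Gnat3 and Lrrc27 was far higher. The matrix metalloproteinase gene Mmp27 was 2.99 (bounds 0.132 to 6.10) in the control and 42.6 (9.25 to 76.1) with sh1137 in the unstranded set (log2 ratio 3.45), and 2.27 and 39.5 in the stranded set (3.63). Pla2g7, which encodes platelet-activating factor acetylhydrolase, was 2.03 and 39.8 in the unstranded and 7.46 and 83.2 in the stranded set. Gnat3, a taste receptor G protein subunit, was 0.381 and 9.37 and, in the stranded set, 0.628 and 20.9. Lrrc27 was 12.8 and 133 in the unstranded set. The protease cathepsin K (Ctsk) was 0.779 and 11.1, and the membrane protein gene Ms4a14 2.45 and 23.6. Genes that were lower included the interferon-inducible Ifi27l2a (146 and 16.2, log2 ratio -3.09), the surface receptor Cd72 (36.6 and 7.42, -2.16), cholesterol 25-hydroxylase (Ch25h, 57.8 and 15.8, -1.81), the fractalkine receptor Cx3cr1 (29.9 and 9.16, -1.61) and the metalloprotease Adam8 (342 and 103, -1.73). In the stranded set, the AP-1 subunit Fosl1 was 23.1 and 3.30 (-2.49), and Ch25h, Adam8 and Cx3cr1 had log2 ratios of -2.56, -2.20 and -2.14. Of 13774 genes tested in the unstranded set, 640 were at least 2-fold higher and 283 lower. The deposited bounds did not overlap for 30 and 2 of these. In the stranded set, 914 of 13436 were higher and 412 lower, with bounds apart for 227 and 46. Without small RNA, clone and predicted gene names, a choice made after seeing the data, the counts were 381 and 145 in the unstranded and 600 and 217 in the stranded set.

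Both 4sU sets of untreated cells shared many of these genes. Of 12484 genes tested in both, 324 were higher in both against 28.2 for independent lists, and 77 were lower in both against 5.70. Opposite calls numbered 25 and 16 (11.8 and 13.6 for independent lists). The higher genes in both sets included Mmp27, Gnat3, Pla2g7, Ctsk and Lrrc27, and the lower ones Cd72, Ch25h, Adam8 and Cx3cr1.

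Several of the genes higher with sh1137 lie near each other. The metalloproteinase genes on chromosome 9 are an example, with Mmp10 at 7502351 to 7510238, Mmp8 at 7558428 to 7568486 and Mmp27 at 7571395 to 7581885. In untreated cells of the stranded set, Mmp8, a neutrophil collagenase, was 5.14 and 43.1 and Mmp10, the protease stromelysin, 0.338 and 8.30. On chromosome 8, the coagulation factor genes F7 (13026033 to 13035809) and F10 (13037307 to 13056676) lie next to each other. F10 was 1.87 and 27.4 after 1 h of LPS in the stranded set, and F7 was 0.219 and 9.99 after 2 h in the unstranded set. Gnat3 (chromosome 5, 17468438 to 17525652) was higher while the nearby Cd36 (17287507 to 17394777), a scavenger receptor, was lower, at 77.5 and 26.6 in the unstranded set.

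After LPS, Lrrc27, Mmp27, Ccl8 and Ccl11 had some of the highest ratios at single times in Wdr82-depleted cells. At 45 min in the unstranded set, Lrrc27 was 8.58 and 99.7, Mmp27 5.26 and 58.2 and the growth factor gene Csf2 2.76 and 27.2. The monocyte chemokine Ccl8 was 0.546 and 18.7 at 2 h (log2 ratio 3.67) and 5.02 and 148 at 4 h (4.63), and the eotaxin gene Ccl11 0.308 and 15.8 at 4 h. Lower genes included Ifi27l2a at 45 min (157 and 16.2), the Fc receptor Fcgr1 at 45 min (25.5 and 6.48), the scavenger receptor Stab1 at 2 h (141 and 39.3), and Cd72 (512 and 115), the fatty acid receptor Gpr84 (78.6 and 21.1) and the arginine synthesis enzyme Ass1 (50.7 and 14.1) at 4 h. After 1 h in the stranded set, Fhad1 was 2.73 and 43.0, and Fosl1 (31.5 and 3.24) and the signalling regulator Rgs16 (45.7 and 6.44) were lower. The counts of higher and lower genes were 1083 and 402 of 13885 at 45 min, 871 and 423 of 13736 at 2 h, and 908 and 455 of 14030 at 4 h. Bounds were apart for 76 and 3, 63 and 3, and 74 and 0 of these. In the stranded set after 1 h the counts were 980 and 566 of 13297 (bounds apart for 265 and 90). At all 4 time points of the unstranded set, 127 of 12241 genes were at least 2-fold higher (0.0353 for independent lists) and 30 lower (0.00248). In a limma fit over these 4 pairs, added after the counts were seen, 1080 genes were higher and 1367 lower at an adjusted p under 0.05, of which 299 and 96 had a mean ratio of at least 2-fold. The total of 2447 calls became 681, 690, 982 and 1547 without the untreated, 45 min, 2 h and 4 h pair, and 114 without the FPKM filter. Mmp27 had a mean log2 ratio of 3.17 (adjusted p 0.00945, higher in 4 of 4 pairs), Ctsk 2.46 (0.00891, 4 of 4), Cd72 -2.07 (0.00848, lower in 4 of 4) and Wdr82 itself -1.01 (0.00871, lower in 4 of 4). The labels do not say whether the times share a transduction, so this error is the spread between times. Without the untreated pair the higher 2-fold count was 207, and without the 4 h pair the lower count was 53. With FPKM of at least 5 the higher count was 61, and with a pseudocount of 0.1 it was 196.

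Genes of DNA replication and of translation were lower as groups in 4sU RNA of untreated Wdr82-depleted cells. Replication-dependent histones, which package newly made DNA, were lower in the unstranded set (median -0.89, percentile 0 among random lists). Of 60 measured histones, 24 were at least 2-fold lower and 1 higher, with Hist1h1b at 169.9 and 62.1 FPKM. Near-identical histone copies share reads, so single members are less certain than the list. Cell cycle genes had a median of -0.57 in the unstranded and -0.57 in the stranded set (percentile 0 in each), with 2 of 26 members 2-fold lower in each. The replication enzyme subunit Rrm2 was 42.4 and 19.6 in the unstranded set. Host transcripts of small RNAs were lower (medians -0.62 and -0.67, percentile 0 in each), among them Snhg5 (39.7 and 16.9) and Snhg12 (87.5 and 50.6). Ribosomal protein genes had medians of -0.31 and -0.21 (percentile 0 in each), with 1 of 75 and 4 of 79 members 2-fold lower. The random lists were not matched on gene length, and genes under 5 kb as a class also had medians of -0.12 and -0.07. These ranks therefore do not separate a list from the length of its genes. Inflammatory LPS genes were slightly higher before LPS (medians 0.15 and 0.23), with the neutrophil chemokine Cxcl3 at 2.74 and 27.8 in the stranded set. The cholesterol exporters Abca1 and Abcg1 were higher in the unstranded set, Abca1 at 5.98 and 13.3 and Abcg1 at 4.57 and 10.7. The mannose receptor Mrc1 was 19.1 and 145 in the stranded set.

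In the unstranded series, interferon and late LPS genes had medians of -0.30 in untreated cells, -0.39 at 45 min, 0.81 at 2 h and -0.07 at 4 h. At 2 h, 16 of 45 members were at least 2-fold higher and 0 lower, among them the T cell chemokine Cxcl9 (2.70 and 44.8), the GTPase Iigp1 (9.66 and 87.6) and nitric oxide synthase (Nos2, 24.3 and 99.3). Inflammatory LPS genes were higher at 45 min (median 0.45, 11 of 58 2-fold higher) and lower at 4 h (median -0.32, 6 of 60 2-fold lower), with Il12b, a subunit of interleukin 12, at 310.5 and 105 at 4 h. Immediate early genes were lower in untreated stranded RNA (median -0.50, percentile 0), with 6 of 22 2-fold lower and 2 higher. Heat shock genes were lower after 1 h of LPS in the stranded set (median -0.52, percentile 0.160), with the chaperone Hsp90aa1 at 212 and 90.9. Genes of the integrated stress and unfolded protein response were lower at 45 min in the unstranded set (median -0.40, percentile 0.100), with the serine synthesis enzyme Psat1 at 17.0 and 7.78. The cystine transporter Slc7a11, which is on the same list, was higher at 7.64 and 39.9.

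**Figure D2:**
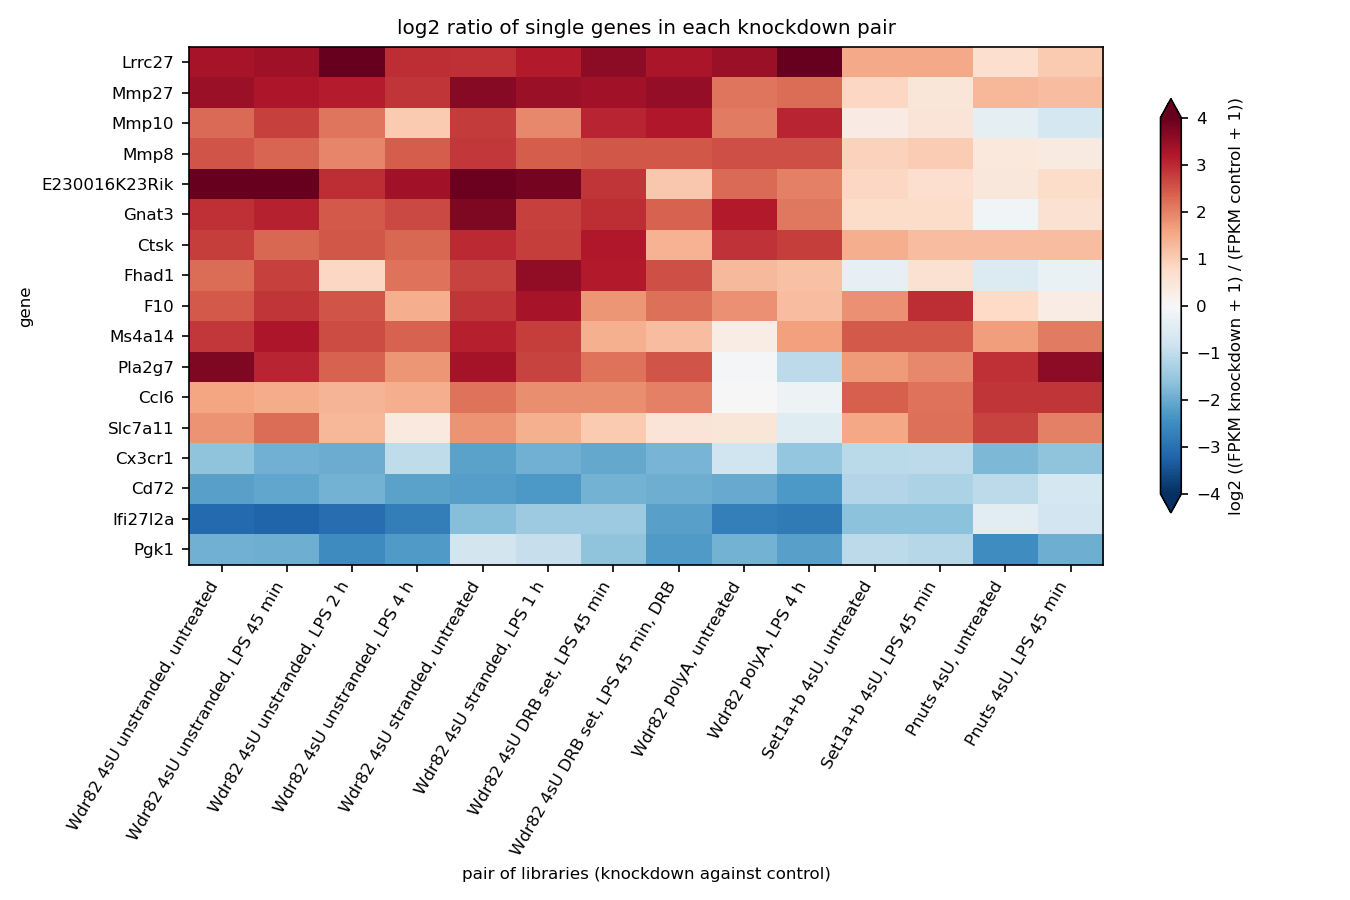
Log2 ratio of knockdown over control (colour) for 17 genes (y axis) in the 14 knockdown pairs (x axis), each from 1 library per condition. Lrrc27 and Mmp27 are above 0 and Cd72 and Pgk1 below 0 in all 14 pairs.

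PolyA RNA of Wdr82-depleted cells showed a different set of leading genes. In untreated cells, cyclin D1 (Ccnd1) was 8.10 in the control and 128 with sh1137 (log2 ratio 3.82), the monocyte chemokines Ccl2 9.43 and 121 and Ccl7 3.92 and 36.8, and the urokinase gene Plau 7.84 and 64.4. Lrrc27 (7.48 and 91.7) and Ctsk (3.28 and 30.9) were higher as in 4sU RNA. Lower genes included the chemokine receptor Ccr2 (50.5 and 7.03, -2.68), the complement subunit C1qb (206 and 37.96, -2.41), apolipoprotein E (Apoe, 5778 and 1208, -2.26) and the lectin Clec10a (201 and 46.1, -2.10). Over the 10 Wdr82 pairs, Clec10a lay above 0 in 8 and Apoe in 6, while Ccr2 and C1qb lay below 0 in 8 and 9. Ccnd1 and Ccl2 lay above 0 in 5 each, Ccl7 in 4 and Plau in 3. After 4 h of LPS, prostaglandin E synthase (Ptges, 75.5 and 9.81) and the scavenger receptor Marco (97.6 and 15.0) were lower. Of 12050 genes, 341 were at least 2-fold higher and 311 lower in untreated cells (bounds apart for 40 and 3). After LPS the counts were 433 and 344 of 12074 (bounds apart for 74 and 11). Named genes alone gave 258 and 210 in untreated cells and 310 and 266 after LPS. The median gene of that pair lay at -0.12, and centring on it changed the higher share of the calls from 55.7% to 67.1%.

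As lists, macrophage markers were lower in both polyA pairs (medians -0.71 and -0.998, percentile 0 in each), with 8 of 19 and 10 of 20 members 2-fold lower. They included the growth factor receptor Csf1r (1062 and 372) and Fcgr1 (156 and 46.7) in untreated cells. Cell cycle genes were higher (medians 0.95 and 0.40), with 12 of 26 2-fold higher in untreated cells, among them the helicase subunits Mcm5 (11.5 and 43.4) and Mcm6 (16.3 and 57.3). This direction is opposite to that in 4sU RNA. The few histones measured in polyA RNA had medians of 0.71 and 0.74 over 8 members, with the linker histone Hist1h1c at 13.5 and 29.0 in untreated cells. Ribosomal protein genes were lower (medians -0.35 and -0.37). Cholesterol and lipid synthesis genes were lower after LPS (median -0.56, percentile 0), with the desaturase Scd1 at 12.9 and 1.84. The B cell genes Ighm (98.7 and 33.3) and Cd79b (16.3 and 5.55) were lower in untreated polyA RNA. Between untreated unstranded 4sU and polyA RNA, 95 genes were higher in both (10.5 for independent lists), 46 lower in both (4.06), and 28 and 17 called in opposite directions (9.12 and 4.69).

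Over all 10 Wdr82 pairs, 468 of 10302 genes lay above 0 in each pair and 499 below 0 in each, against 10.1 in each direction if signs were random and the pairs independent. At least 2-fold in all 10 pairs were 32 genes in the higher direction and 2, Cd72 and Ifi27l2a, in the lower. The glycolytic enzyme gene Pgk1 was lower in all 14 knockdown pairs, with log2 ratios from -2.51 to -0.74. In untreated unstranded RNA Pgk1 was 193 and 49.9. These ratios do not separate a fall with the hairpin from an excess in the control, because no library without a vector was measured.

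With hairpins against Set1a and Set1b, which encode the catalytic subunits of the Set1 complexes, the MHC class II genes H2-Ab1 and Cd74 were higher in 4sU RNA. Dendritic cell and MHC class II markers had medians of 1.06 in untreated cells and 0.97 after 45 min of LPS (percentiles 99.99 and 99.98), with 4 of 7 and 4 of 8 members 2-fold higher. In untreated cells the MHC chain H2-Ab1 was 12.3 (bounds 5.44 to 19.1) in the control and 32.4 (15.3 to 49.4) in the knockdown, and the invariant chain Cd74 39.7 and 89.7. H2-Ab1 and Cd74 lay above 0 in all 14 knockdown pairs, and the list median was 0.62 in untreated unstranded and 0.54 in untreated stranded 4sU RNA with sh1137 (percentiles 99.4 and 94.7), against 0.09 in untreated Pnuts cells. The calprotectin gene S100a8 (2.17 and 18.4), the chemokine Ccl6 (98.7 and 521), the lectin Clec4n (14.3 and 60.1) and Ms4a14 (3.57 and 24.03) were among the highest ratios. After LPS, F10 was 2.04 and 22.3, the decoy receptor Il1r2 4.91 and 29.3 and the acute phase gene Saa3 6.10 and 30.0. Lower genes in untreated cells included Slfn4, of the Schlafen family (19.8 and 0.784, log2 ratio -3.55), the helix-loop-helix inhibitor Id3 (21.9 and 5.45), the complement subunit C1qa (63.7 and 19.2), and the antiviral Oasl1 (11.4 and 3.12) and Oas3 (25.9 and 8.26). After LPS, the kinase Dmpk was 23.6 and 3.23.

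By list in the Set1a+Set1b set, p53 targets were higher (medians 0.54 and 0.42, 3 of 19 and 3 of 20 2-fold higher), with the stress protein gene Trp53inp1 at 9.44 and 28.9 in untreated cells. Neutrophil and granule markers had medians of 0.70 over 7 members and 1.02 over 8. Inflammatory LPS genes were higher after LPS (median 0.43, 11 of 58 2-fold higher), with Csf2 at 2.43 and 23.5. Interferon and late LPS genes were lower (medians -0.23 and -0.26), with 4 of 41 2-fold lower and 3 higher in untreated cells. Histones (medians -0.99 and -1.25) and cell cycle genes (-0.29 and -0.38) were lower, and no cell cycle gene reached 2-fold. Of 12840 genes, 325 were 2-fold higher and 223 lower in untreated cells (bounds apart for 68 and 30). After LPS, 447 and 323 of 12880 were called (bounds apart for 111 and 59). Without small RNA, clone and predicted gene names, 154 and 94 remained in untreated cells and 261 and 129 after LPS, and a pseudocount of 0.1 gave 626 and 375 in untreated cells and 734 and 523 after LPS.

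In cells labelled Pnuts sh, genes of the integrated stress response were higher, and Id1, Id3 and Smad6 were lower. The integrated stress and unfolded protein response list had medians of 0.83 in untreated cells and 0.91 after 45 min of LPS (percentile 100 in each), with 7 and 9 of 19 members 2-fold higher and none lower. In untreated cells Slc7a11 was 1.36 (bounds 0.503 to 2.21) in the control and 14.3 (6.74 to 21.8) in the knockdown, the stress transcription factor Atf5 5.96 and 37.3, the pseudokinase Trib3 5.73 and 35.7 and the serine synthesis enzyme Phgdh 2.17 and 13.8. The macrophage apoptosis inhibitor Cd5l (0.725 and 22.4), the gelatinase Mmp9 (0.560 and 14.3), Pla2g7 (3.50 and 32.9), Ccl6 (43.6 and 322) and histidine ammonia-lyase (Hal, 16.4 and 112) were among the highest ratios, and after LPS the stress cytokine Gdf15 was 12.3 and 105. The BMP-responsive genes Id3 (113 and 15.9), Id1 (178 and 29.4) and Smad6 (14.5 and 2.11) were lower in untreated cells, as were Pgk1 (233 and 40.7) and Ch25h (83.1 and 17.3). The ligand gene Bmp2 was 1.37 and 16.2 after LPS. The uridine kinase gene Uck2 was 297 in the control after LPS and listed at 0 in the knockdown, but it was listed at 0 in 14 of the 28 libraries and between 7.68 and 1459.92 in the others.

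By list in the Pnuts set, histones (medians -0.85 and -1.59) and cell cycle genes (-0.93 and -1.03) were lower, each at percentile 0 in both pairs. After LPS, 55 of 60 histones and 15 of 26 cell cycle genes were 2-fold lower, among the latter the mitotic activator Cdc20 (22.2 and 5.88). Interferon and late LPS genes were lower (medians -0.46 and -0.30), with Irf7, their transcription factor, at 44.7 and 20.7 in untreated cells. Macrophage markers had a median of 0.22 in untreated cells (percentile 99.4), with lysozyme (Lyz1) at 265 and 832 and Mrc1 at 13.8 and 52.4. Neutrophil and granule markers were lower (medians -0.62 and -1.01), although Mmp9, which is on that list, was higher. The cholesterol and lipid synthesis list was higher after LPS (median 0.68, 7 of 20 2-fold higher). Abca1, a cholesterol exporter and not a synthesis gene, was 3.70 and 19.8. Immediate early genes were at -0.27 before and 0.59 after LPS, and inflammatory LPS genes at -0.22 and 0.37. Of 12820 genes, 433 were 2-fold higher and 322 lower in untreated cells (bounds apart for 71 and 30). After LPS the counts were 834 and 503 of 13039 (bounds apart for 128 and 70), and centring on the median gene (0.08) gave 685 and 584. With small RNA, clone and predicted names left out, the Pnuts counts were 280 and 165 in untreated cells and 583 and 265 after LPS. Ppp1r10 itself was not reduced in these libraries.

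The 3 knockdowns shared genes in untreated 4sU RNA. The Wdr82 control held an empty vector and the Set1a+Set1b and Pnuts controls a scrambled hairpin, so the contrasts are not alike. Of 12160 genes tested in the stranded Wdr82, Set1a+Set1b and Pnuts pairs, 36 were at least 2-fold higher in all 3 (0.314 for independent lists) and 13 lower (0.0719). Higher in all 3 were Ccl6, Pla2g7, Ms4a14, Ms4a7, Ctsk, Slc7a11, the lysosomal glycoprotein Gpnmb, the lectin Clec4n, the fatty acid binding protein Fabp5 and the ectonucleotidase Entpd1, of which Ms4a7, Gpnmb, Fabp5 and Entpd1 were chosen after their values were seen. Lower in all 3 were Cd72, Cx3cr1, the sulfotransferase Chst3, Dmpk, nestin (Nes) and 8 histone genes. By pair, Wdr82 and Pnuts shared 138 higher (18.3 for independent lists) and 64 lower genes (6.57), with 25 and 19 opposite (13.2 and 9.14). Wdr82 and Set1a+Set1b shared 90 higher (13.7) and 45 lower (4.41), with 18 and 19 opposite (9.03 and 6.70). Set1a+Set1b and Pnuts shared 69 higher (7.44) and 42 lower (3.51), with 33 and 18 opposite (5.68 and 4.60), so opposite calls were also more frequent than independence gives.

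**Figure D3:**
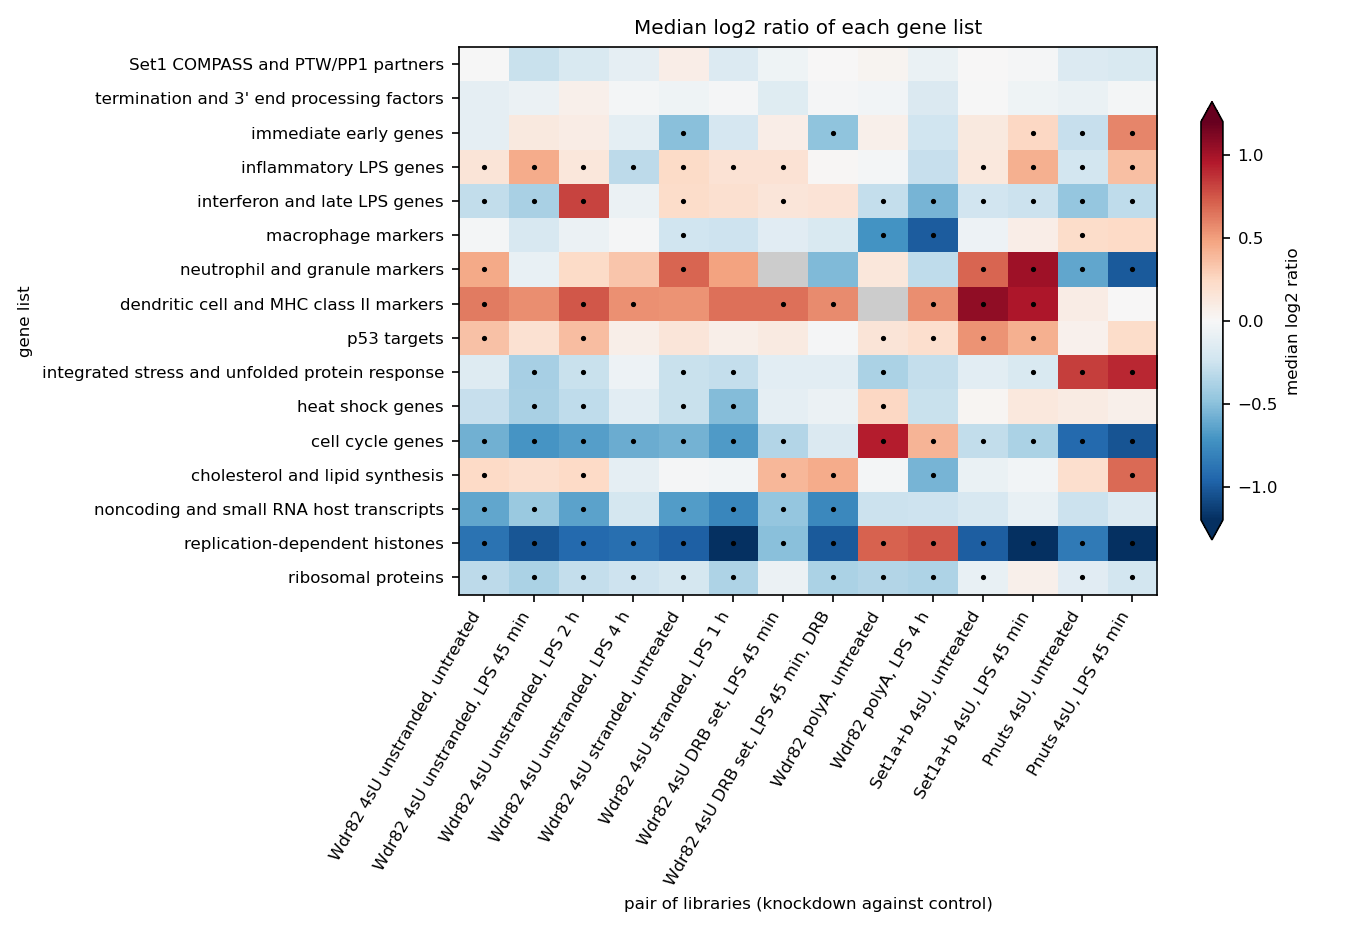
Median log2 ratio of knockdown over control (colour) for 16 gene lists (y axis) in the 14 knockdown pairs (x axis). Dots mark medians outside the central 95% of random lists, and grey marks fewer than 5 measured members. Histones are lower in the 12 4sU pairs and higher in both polyA pairs, where few members were measured.

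In control cells given LPS, immediate early and inflammatory genes were higher at 45 min, and interferon genes were highest at 4 h. In the unstranded 4sU set, immediate early genes were higher at 45 min (median 2.91, 21 of 23 2-fold higher), with the transcription factor Egr1 at 2.84 before and 362 after, and less so at 2 h (0.81) and 4 h (0.93). Inflammatory LPS genes had medians of 3.14 at 45 min and 4.45 at 4 h, with 59 of 60 2-fold higher at 4 h. The neutrophil chemokine Cxcl1 was 5.94 and 2073 at 45 min and the cytokine Il1b 0.777 and 2182 at 4 h. Interferon and late LPS genes were at 0.11, 2.74 and 5.33 at 45 min, 2 h and 4 h, with 43 of 44 2-fold higher at 4 h, the chemokines Cxcl10 (2.95 and 9156) and Ccl5 (3.32 and 6578) among them. Cell cycle genes were lower at 2 h (-0.41) and 4 h (-1.10, 16 of 26 2-fold lower). Lower genes at 4 h included the helix-loop-helix inhibitor Id1 (123 and 16.8), Plau (335 and 8.67) and the chemokine receptor Cxcr4 (143 and 3.85). Dendritic cell and MHC class II markers, taken as a list, were higher at all 3 times (medians 1.40, 1.21 and 1.36). The counts of higher and lower genes were 748 and 540 of 13522 at 45 min, 1529 and 913 of 13674 at 2 h and 2780 and 1509 of 13955 at 4 h.

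The same lists were higher in the other sets. After 45 min of LPS, immediate early genes had medians of 2.48 in the Pnuts and 2.54 in the Set1a+Set1b controls, and inflammatory LPS genes 2.72 and 2.58. After 1 h in the stranded Wdr82 control the immediate early median was 0.43 and the inflammatory median 2.37. In polyA RNA after 4 h, inflammatory genes were at 4.101 and interferon genes at 4.22, with all 45 measured members 2-fold higher, and Cxcl10 at 2.98 and 9611. The counts of higher and lower genes in the controls were 671 and 372 (Pnuts set), 668 and 369 (Set1a+Set1b set), 493 and 385 (stranded Wdr82 set) and 2274 and 1053 (polyA set). With the hairpins they were 1055 and 488, 755 and 422, 553 and 519, and 1979 and 731. In the unstranded set with sh1137 they were 1160 and 485 at 45 min, 1816 and 1134 at 2 h, and 3019 and 1615 at 4 h. The median gene lay above 0 after 4 h of LPS, at 0.19 and 0.16 in 4sU RNA of control and sh1137 cells, 0.19 and 0.13 in polyA RNA, and at 0.10 after 45 min in the Pnuts sh libraries. Centring changed the higher share of the calls from 64.8% to 53.6% in the 4 h 4sU control, from 68.3% to 55.7% in the polyA control, and from 68.4% to 57.6% in the Pnuts sh libraries. In the stranded Wdr82 control after 1 h it went from 56.2% to 47.5%, so that lower genes were then the majority.

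**Figure D4:**
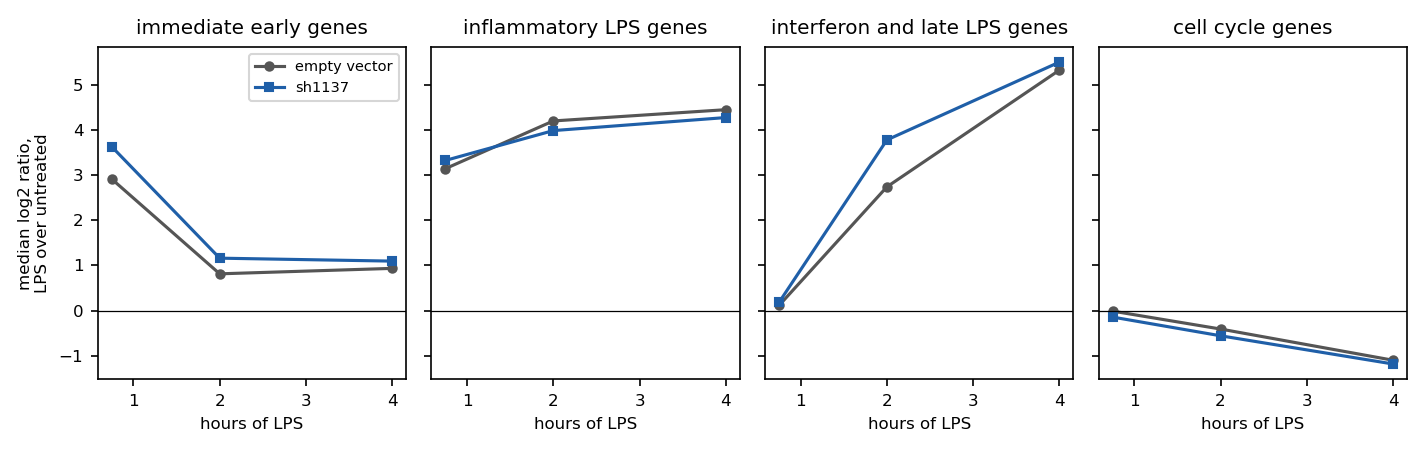
Median log2 ratio of LPS over untreated (y axis) against hours of LPS (x axis) for 4 gene lists in the unstranded 4sU set, with empty vector (circles) and sh1137 (squares), 1 library per point. The interferon list at 2 h stands at 2.74 with empty vector and 3.78 with sh1137.

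With Wdr82 depletion, interferon genes had higher LPS ratios at 2 h in 4sU RNA, and inflammatory genes lower ones at 4 h. In the unstranded Wdr82 set at 2 h, the LPS log2 ratio of Cxcl9 was 1.89 in the control and 5.52 with sh1137, that of the GTPase gene Tgtp1 0.32 in the control and 4.18, and that of the serpin Serpina3g 2.16 in the control and 5.78. The interferon list differed there by a median of 0.95. At 4 h, Ccl8 was at 2.59 in the control and 6.67 with sh1137, while Ptges (5.41 in the control and 2.37), the neutrophil chemokine Cxcl3 (7.64 in the control and 4.71), Csf2 (4.86 in the control and 2.31) and Il1a (8.52 in the control and 6.34) had lower LPS ratios, and the inflammatory list differed by -0.47 and the interferon list by 0.31. Cxcl3 was already higher with sh1137 before LPS (0.204 and 4.76), which lowers its LPS ratio, and was 239.7 and 150.2 at 4 h. As given above, the interferon list was lower with sh1137 before LPS and not higher at 4 h. Its higher LPS ratio at 4 h therefore goes with lower untreated values. The inflammatory list was slightly higher before LPS and lower at 4 h, and both lower its LPS ratio. At 45 min Csf2 responded more (1.91 in the control and 4.65), and the immediate early and inflammatory lists differed by 0.26 and 0.30. In polyA RNA at 4 h, Ptges (5.10 in the control and 2.34) and Tnf (8.18 in the control and 5.48) had lower LPS ratios, for Tnf mostly because its untreated value was higher with sh1137 (3.93 and 25.7 before and 1428 and 1194 after LPS), and the inflammatory, interferon, heat shock and cholesterol lists differed by -0.42, -0.23, -0.68 and -0.58, the interferon list inside the random range. In the Pnuts set the immediate early and inflammatory lists responded more (0.71 and 0.64), with Il10, an inhibitory cytokine, at 0.95 in the control and 2.90 with the hairpin. Both lists were lower with that hairpin before LPS and higher after it, and both add to these differences. In the Set1a+Set1b set these lists differed by 0.21 and 0.24, with Csf2 at 1.78 in the control and 4.62 with the hairpins. After 1 h in the stranded Wdr82 set they differed by -0.07 and -0.01, and the kinase gene Src responded more (0.37 in the control and 3.67 with sh1137). Of the genes induced 2-fold in the control, 65.4% were also induced 2-fold with the hairpin in the Pnuts set, 62.7% in the Set1a+Set1b set, 45.0% in the stranded Wdr82 set, 70.3%, 73.1% and 78.3% at 45 min, 2 h and 4 h in the unstranded set, and 71.2% in polyA RNA. These are differences of ratios from 4 libraries each and were not tested. The induced genes were chosen by the control ratio, so some loss in the other pair follows from the choice alone. More genes were induced with the hairpin than in the control in each 4sU set (1055 against 671 in the Pnuts set) and fewer in polyA RNA (1979 against 2274). The shares therefore do not show a general loss of induction.

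In LPS-treated cells given DRB, 4sU RNA of immediate early and inflammatory genes was lower. The interferon regulatory factor Irf1 was 540.2 (bounds 43.0 to 1050.3) without and 24.9 (6.24 to 43.7) with DRB in scrambled control cells (log2 ratio -4.38), and 489 and 20.4 with sh1137. The mRNA decay factor Zfp36 was 877 and 42.6, and the stress protein gene Gadd45b 91.8 and 4.15 in scrambled cells. Immediate early genes had medians of -1.93 with scrambled and -2.37 with sh1137 (16 of 21 and 17 of 22 2-fold lower), inflammatory LPS genes -2.40 and -2.47, stress response genes -0.996 and -1.19, and small RNA host transcripts -1.52 and -1.58. p53 targets were lower (-0.50 and -0.75), although the ribonucleotide reductase subunit Rrm2b was higher (3.56 and 45.7 in scrambled cells). Histones (1.56 and 1.02) and macrophage markers (0.98 and 0.91) were higher, with the receptor kinase Mertk at 8.84 and 38.4 in scrambled cells. With scrambled hairpin, 2134 genes were 2-fold higher and 2046 lower of 13037 (bounds apart for 179 and 293). With sh1137 the counts were 1785 and 2057 of 13307 (bounds apart for 84 and 305). FPKM are relative to the library total, so a fall shared by most genes is not visible in them. The median gene lay at 0.15 and 0.21, and centring changed the higher share of the calls from 51.1% to 39.4% and from 46.5% to 27.5%.

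Among the length classes, the longest genes had the highest median DRB ratios. Genes over 100 kb had median log2 ratios of 1.14 with scrambled (497 genes, 58.6% at least 2-fold higher) and 0.88 with sh1137 (506 genes, 40.7%). Genes of 20 to 50 kb had medians of -0.14 and -0.07, genes of 5 to 20 kb -0.07 and 0.01, genes of 50 to 100 kb 0.29 and 0.23, and genes under 5 kb 0.41 and 0.35. Of the genes under 5 kb, 20.5% were at least 2-fold higher and 14.0% lower with scrambled, and 17.1% and 16.1% with sh1137. After centring on the median gene, genes under 5 kb were at 0.26 and 0.14, and the class of 5 to 20 kb with sh1137 was at -0.20.

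**Figure D5:**
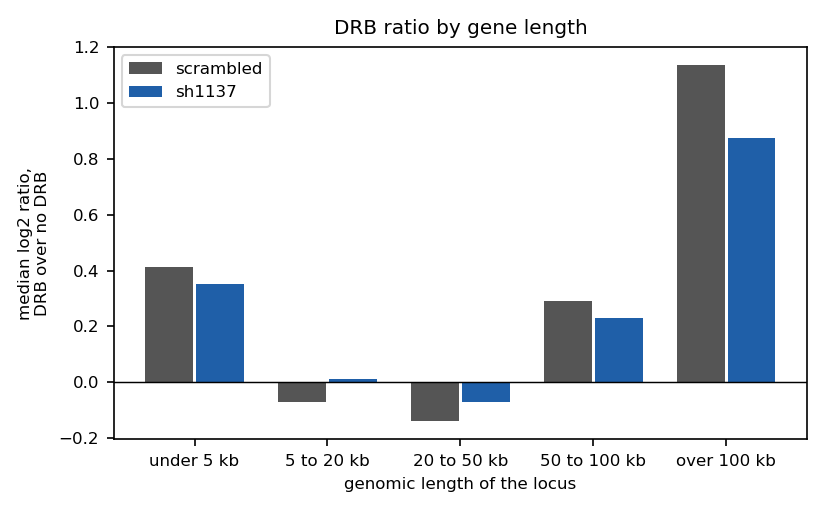
Median log2 ratio of DRB over no DRB (y axis) by genomic length of the locus (x axis), with scrambled hairpin and with sh1137, 1 library per condition. Bars for genes over 100 kb reach 1.14 and 0.88.

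With LPS for 45 min in this set, Wdr82 depletion gave higher Lrrc27 (6.72 and 90.5), Ctsk (2.13 and 27.9) and Mmp27 (2.18 and 31.6), and lower Cx3cr1 (19.7 and 3.98) and Cd72 (31.8 and 7.75), without DRB. With DRB, Mmp27 (2.22 and 35.98) and Lrrc27 (14.2 and 144) were higher, and Pgk1 (166 and 33.5) and Ifi27l2a (217 and 47.0) lower. Without DRB 477 genes were 2-fold higher and 202 lower of 12866 (bounds apart for 38 and 1). With DRB 513 were higher and 604 lower of 12847, but with bounds apart for 28 and 12 the higher genes were the majority. Small RNA host transcripts were lower in both pairs (-0.46 and -0.78), with Snhg5 at 8.93 and 2.23 with DRB. Cholesterol and lipid synthesis genes were higher (0.40 and 0.45).

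The series title concerns early termination, and the knockdown ratios were therefore also compared by gene length and position. In the stranded Wdr82 set of untreated cells, genes under 5 kb had a median of -0.07 (percentile 0) and genes over 100 kb a median of 0.18 (percentile 100). In untreated unstranded 4sU RNA the medians were -0.12 and 0.08, after 45 min in the Pnuts set -0.08 and 0.24, and after 45 min in the Set1a+Set1b set -0.08 and 0.08. No such order appeared in the DRB set without DRB (-0.02 and -0.04, percentiles 41.4 and 42.6), while in untreated polyA RNA genes under 5 kb were at -0.09 (percentile 0.03) and long genes at -0.03 (percentile 64.3). With DRB, genes over 100 kb were lower with sh1137 (median -0.33, percentile 0). Low genes within 5 kb of an active locus had medians of 0.08, 0.29, 0.14 and 0.21 in untreated cells and at 45 min, 2 h and 4 h in the unstranded Wdr82 set (percentiles 96.4, 100, 99.5 and 99.8). Those 5 to 20 kb away were at 0.09, 0.19, 0.10 and 0.22 (percentiles 95.9, 88.2, 85.1 and 99.6), and those over 20 kb away at 0.0086, 0.07, 0.03 and 0.03 (percentiles 6.57, 0.425, 4.19 and 0.065). In polyA RNA low genes within 5 kb were at -0.03 (percentile 51.5) in untreated cells and at 0.15 (percentile 99.5) after 4 h of LPS. In the DRB set they were at 0.09 (percentile 84.9) without DRB and at -0.07 (percentile 4.48) with it. In the stranded set the medians were 0.04 and 0.11 (percentiles 22.1 and 81.6), in untreated Set1a+Set1b cells -0.04 (percentile 0.2), and in untreated Pnuts cells 0.09 (percentile 73.8). The strand of the neighbours was not used.

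The lists of genes of the complexes around WDR82 and of transcription termination had medians near 0, while single members moved. Zc3h4 (log2 ratios 0.30 to 1.45), Ints6 (0.29 to 1.60) and Ints3 (0.48 to 1.23), chosen after their values were seen, lay above 0 in all 10 Wdr82 pairs, as did Ppp1r10 (0.72 to 1.60). Others, also chosen after their values were seen, went the other way. Cpsf3l (-0.65 to -0.17), Cpsf3 (-0.48 to -0.11), Cpsf2 (-0.41 to -0.02) and Hcfc1 (-0.77 to -0.18) lay below 0 in all 10 pairs. Ints9 and Ints1 lay below 0 in 8 and 7 of 10. Set1 COMPASS and PTW/PP1 partners had medians between -0.26 and 0.08 over the 14 knockdown pairs, and termination and 3' end processing factors between -0.18 and 0.06, none outside the random range. The list of 4 targeted genes, given singly above, was too short for a rank. Lymphocyte markers had at most 4 measured members, erythroid markers at most 2 and mast cell and basophil markers at most 1. Stromal markers reached 6 members in the Pnuts set, where their median in untreated cells was -0.53 (percentile 0.8). The 37 mitochondrially encoded genes had no member with status OK and sufficient FPKM. Medians of snoRNA, scaRNA and snRNA genes ranged from -0.73 to 2.59 and those of microRNA genes from -0.96 to 6.94 over the knockdown pairs.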

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

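The 3 tests of explanations in this part, and the rule that set polyA against 4sU pairs, were chosen only after the results were seen.

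In 4 cases the list medians of gene groups moved in opposite directions with sh1137 under different conditions. None of these differences was tested. Inflammatory LPS genes were higher with sh1137 in the unstranded 4sU set at 45 min and lower at 4 h, with 0.76 between the highest and the lowest list median (log2). At 4 h the lower members included Il12b (310.5 and 105) and Csf2 (28.0 and 4.58). Interferon and late LPS genes were lower before LPS and at 45 min and higher at 2 h in the same set, with 1.205 between the lowest median, at 45 min, and the highest, at 2 h. Cxcl9 was 2.70 and 44.8 at 2 h. Replication-dependent histones lay below 0 in the 8 Wdr82 4sU pairs (medians from -1.31 to -0.51) and above 0 in both polyA pairs, a difference of means of 1.67. Mature replication-dependent histone mRNA ends without a polyA tail, so polyA RNA held few members of this list (8 in untreated cells). The difference of means therefore sets different members against each other. Among histone genes measured in all 10 Wdr82 pairs, Hist2h2be lay above 0 in 9, and Hist1h2bc, Hist1h4i, Hist1h1c and Hist3h2a below 0 in 8, 9, 7 and 7. Cell cycle genes lay below 0 in the 8 4sU pairs (medians from -0.70 to -0.18) and above 0 in both polyA pairs, a difference of means of 1.21, and Mcm5 was 43.4 and 30.3 in untreated unstranded 4sU RNA and 11.5 and 43.4 in untreated polyA RNA.

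The cell cycle pattern was weighed against scaling, the state of the cultures and RNA kinetics. Scaling of the libraries is argued against only as far as the median gene shows it. The median gene lay below 0 in both polyA pairs (-0.055 in untreated cells and -0.12 after LPS), opposite to the cell cycle genes. Centring on it could therefore only raise the polyA list medians, which became 1.00 and 0.52. Another state of differentiation in the polyA cultures stays a candidate explanation, since macrophage markers were lower with sh1137 in polyA RNA by 0.46 beyond the lowest 4sU median (-0.25), with Csf1r at 1062 and 372 in untreated cells. Newly made RNA and RNA level going apart in the same cells also stays open. Between untreated unstranded 4sU and polyA RNA, 45 genes were 2-fold apart in opposite directions and 141 in the same, but no label ties the 4sU and polyA RNA to the same cultures, so these explanations cannot be told apart.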

How the results depend on the processing

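The alternatives without small RNA, clone and predicted gene names and without the snoRNA and microRNA lists were tests chosen only after the results were seen, as were the choice to judge the total of called genes per comparison and the 95% binomial interval of a median as the bound for a move. Depth limits the low genes, since relative depth within a set differed by an estimated 3.35-fold at most and the tables hold no read counts. That highest value is from the polyA set, where the estimate is the least certain. The fit over the 4 pairs of the unstranded set, also chosen after the results were seen, measures the spread between times and not between cultures.

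Of the 30 counts of called genes, 30 stayed within 1.5 times under median centring (0.947 to 1.04 of the count), 20 with FPKM of at least 5 (0.526 to 0.840), 15 with a pseudocount of 0.1 (1.21 to 1.83) and 10 without small RNA, clone and predicted names (0.453 to 0.847). Dropping the FPKM filter changed no count, by construction, because a 2-fold call with a pseudocount of 1 needs an FPKM of at least 1. Of 539 list medians, 20 moved and 2 reversed under centring, 9 moved without the filter and 7 with a pseudocount of 0.1. With FPKM of at least 5, 478 could be computed, and 1 reversed. Of 2732 ratios of named genes, none reversed under centring or the pseudocount, but 2548 and 2554 moved. A move was counted for any change of the log2 ratio at 2 decimals, so these numbers do not measure how far the ratios changed. The knockdown lists outside the random range numbered 133, and 118 without the filter, 134 with a pseudocount of 0.1, 114 with FPKM of at least 5, 133 after centring and 117 without the snoRNA and microRNA lists. For LPS they numbered 121, with 98 to 121 under the alternatives, and for DRB 22, with 19 to 22.

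With a pseudocount of 0.1, which raises ratios of low genes, the called genes in knockdown pairs numbered 1266 (Pnuts untreated), 1001 and 1257 (Set1a+Set1b untreated and 45 min), 1149 and 1797 (without and with DRB), 2017 (stranded Wdr82 untreated), 1519, 2349, 2037 and 2124 (unstranded untreated, 45 min, 2 h, 4 h), and 1077 and 1225 (polyA untreated and 4 h). For LPS they were 1384 and 1677 (stranded control and sh1137) and 1981 (unstranded control, 45 min). Higher at all 4 times were 196 genes, and in both 4sU experiments 519 higher and 125 lower. DRB medians were 0.48 and 0.40 (scrambled and sh1137) under 5 kb and 1.29 and 1.01 over 100 kb.

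With FPKM of at least 5, which tests fewer genes, the counts were 357 and 627 (without and with DRB), 845 and 976 (stranded Wdr82 untreated and 1 h), 630 (stranded LPS, sh1137), 564, 892, 741 and 784 (unstranded untreated, 45 min, 2 h, 4 h) and 836 (unstranded control, LPS 45 min). Higher at all 4 times were 61 genes, and in both experiments 194. The p53 list after LPS in polyA RNA went from 0.20 to -0.0036, for a cause that was not tested. DRB medians were 0.54 and 0.51 under 5 kb, 0.0781 at 5 to 20 kb (sh1137), and 1.22 and 0.95 over 100 kb, and the cause was not tested.

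Centring, which subtracts the median gene, took the LPS medians of the Set1a+Set1b control from 0.0072 to -0.0649 for cell cycle and from 0.06 to -0.0094 for ribosomal protein genes. The DRB medians with scrambled became 0.26, -0.23, -0.29, 0.14 and 0.98 in order of length class, and with sh1137 0.14, -0.20 (from 0.01), -0.28, 0.0202 and 0.67.

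Without small RNA, clone and predicted names, fewer genes are tested, and the counts were 445 and 848 (Pnuts untreated and 45 min), 662 and 1028 (LPS, scrambled and Pnuts sh), 248 and 390 (Set1a+Set1b untreated and 45 min), 628 and 748 (LPS, scrambled and Set1a+Set1b sh), 364 and 654 (without and with DRB), 817 and 960 (stranded Wdr82 untreated and 1 h), 468 and 536 (stranded LPS, control and sh1137), 526, 896, 758 and 746 (unstranded untreated, 45 min, 2 h, 4 h), and 765 and 1015 (unstranded LPS 45 min, control and sh1137).

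Without the untreated pair, genes higher at the remaining times numbered 207 (127 with it), and without the 4 h pair genes lower numbered 53 (30 with it), since fewer pairs have to pass. The limma fit over the 4 pairs called 2447 genes, 2154 with a pseudocount of 0.1, 2155 with FPKM of at least 5 and 2417 after centring. It called 114 without the filter, where 33212 genes were tested, and 681, 690, 982 and 1547 without the untreated, 45 min, 2 h and 4 h pair, where 1 residual degree of freedom fewer is left. Of the 8 ways to exchange knockdown and control within the 4 pairs, 1, the real one, gave as many genes, and the highest of the others gave 0. With 8 such splits a share under 0.05 is not possible.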

Other observations

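Of the tests in this part, that of background reads by the ratio of receptor FPKM was set before its result was seen. The tests of Pgk1 with the glycolytic genes, of neighbouring genes, of Ppp1r10, of background reads by size and over many silent genes, and of long genes were chosen only after the results were seen.

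Pgk1, the gene for phosphoglycerate kinase on chromosome X (103382438 to 103399038), was lower in 14 of 14 knockdown pairs, with a median log2 ratio of -1.94. It was 192 and 32.9 at 2 h of LPS in the unstranded Wdr82 set and 137 and 36.2 in untreated polyA RNA. Other glycolytic genes, chosen after the value of Pgk1 was seen, had smaller medians, although Tpi1 after 1 h of LPS in the stranded Wdr82 set was at -1.01 and Pgk1 at -0.92. Their medians over the 14 pairs were -0.41 for Aldoa, -0.33 for Eno1, -0.33 for Gapdh, -0.39 for Ldha, -0.48 for Tpi1, -0.09 for Pgam1 and -0.05 for Pkm2. In untreated polyA RNA, Pkm2 (521 and 824), Tpi1 (88.3 and 123) and Eno1 (22.4 and 35.2) were higher with sh1137 while Pgk1 was lower. Most of the spread in Pgk1 lay in the controls. Its control FPKM ranged from 46.3 (stranded Wdr82 set, 1 h of LPS) to 248 (unstranded Wdr82 set, 45 min). With the hairpins it was at most 62.8 (unstranded Wdr82 set, 45 min). All libraries carried a vector, so a loss of Pgk1 RNA with the hairpins is not separated from additional Pgk1 reads in the controls. No explanation for Pgk1 was tested.

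In the 8 Wdr82 4sU pairs, genes higher with sh1137 lay beside each other more often than in any shuffle. Lower genes did too, except at 4 h in the unstranded set and without DRB in the DRB set. In untreated cells of the stranded set, 62 neighbouring pairs were both 2-fold higher, against a mean of 25.5 and a highest of 42 in 1000 shuffles within expression bins. After 1 h of LPS there were 83 (mean 34.1, highest 55). In the unstranded set there were 33 (mean 11.8, highest 23) in untreated cells and 74, 63 and 68 at 45 min, 2 h and 4 h (highest 57, 44 and 46). F7 and F10, and Mmp10, Mmp8 and Mmp27, lie close together on their chromosomes. Lower genes with sh1137 formed 24 pairs (highest 15) in the untreated stranded and 20 (highest 8) in the untreated unstranded set. In polyA RNA the higher genes formed 12 and 15 pairs (highest 12 and 17), and the lower genes 17 and 23 (highest 11 and 14). With the Pnuts hairpin the higher genes formed 10 pairs in untreated cells (highest 14) and 40 after LPS (mean 24.8, highest 40). With the Set1a+Set1b hairpins they formed 11 (highest 11) and 14 (highest 16). Lower genes in untreated cells formed 13 pairs in the Pnuts set (highest 11) and 15 in the Set1a+Set1b set (highest 7). Of these, 7 and 13 were pairs of histone genes. Lower genes after LPS formed 57 pairs in the Pnuts set (highest 22) and 45 in the Set1a+Set1b set (highest 12), of which 42 and 32 were pairs of histone genes, as were 11 of the lower pairs with sh1137 in each untreated 4sU set.

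Uck2 was listed at 0 in 14 of 28 libraries and between 7.68 and 1459.92 in the others. No ratio of Uck2 is read as a change.

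Ppp1r10, the gene for PNUTS, was higher in the libraries labelled Pnuts sh (89.5 and 144 in untreated cells). An exchange of knockdown and control in that set was weighed by the genes shared with the Wdr82 knockdown. In untreated cells, 202 genes were 2-fold apart in the same direction and 44 in opposite directions, but no table shows that both knockdowns must act alike, so this is not decided. Newly made RNA hiding the loss of finished mRNA is a candidate explanation for the absence of a fall. The lowest log2 ratio of Wdr82 was -1.13 in the 4sU pairs without DRB, against -1.92 and -2.23 in polyA RNA, although the DRB-treated 4sU pair was also at -1.92, and this would not explain a rise. A response of Ppp1r10 to loss of its complex may account for the rise, since Ppp1r10 lay above 0 in 10 of 10 Wdr82 pairs.

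Many genes were higher with DRB, such as Mertk (8.84 and 38.4 in scrambled cells). Background reads, judged by mean FPKM of 1197 olfactory receptor genes, the odorant receptors of the nose, were 2.19-fold higher with DRB at the lower and 6.17-fold at the higher of the 2 ratios. By the criterion set beforehand, a ratio of at least 1.5 with both vectors, this came out for background reads. That test rests on the receptor gene Olfr267 (2.03 and 81.8 in scrambled cells), and without it the ratios were 0.74 and 1.86. The size of the receptor values, with or without Olfr267, does not decide on background reads. The criterion on size was written after the ratios were seen, and for the receptors without Olfr267 it replaced an earlier criterion on their ratio. With DRB the receptor genes averaged at most 0.0933 FPKM, and 0.02496 without Olfr267, while genes 2-fold higher with DRB gained a median of at least 13.4 FPKM. A 2-fold call with a pseudocount of 1 needs a gain of at least 1 FPKM, so receptor values this low had to lie far below it. Silent genes also cannot show background from the RNA of expressed genes. Polymerases already inside long genes when DRB was added, and still labelling RNA, are a candidate explanation for the long genes. Genes over 100 kb had medians of 0.88 and 1.14, while those of genes under 5 kb (0.35 and 0.41, or 0.14 and 0.26 after centring on the median gene) stay without an explanation. With sh1137, 17.1% of the genes under 5 kb were 2-fold higher and 16.1% lower.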
